A study of Triticum aestivum with 12 samples.

How the data were processed

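Embryo and endosperm of field-grown bread wheat, cultivar Zhou 8425B, were sampled at 14 and 25 days post anthesis (DPA), the endosperm together with episperm and pericarp, with 3 biological replicates in each of 4 groups. The 12 libraries were sequenced as paired ends. Groups were taken from the sample descriptions, because the stage characteristic of 6 of the 12 samples contradicts the description. The submitters name TopHat and DESeq in their processing notes, and the versions and the genome build are not given in the sources used here.

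The deposited gene values per library are counts of uniquely mapped reads, per the file headers, and genes without a read are not listed. The deposited RPKM values are reads per kilobase of coding length relative to the library total, by the authors, and 99.9% of them lay within 0.1% of the value recomputed from count, length and total. The deposited joined gene table holds the same counts for 82913 genes, and its counts were checked to be equal in all of them. A deposited table of 63209 non-redundant transcripts, built by the authors from RNA-Seq and Iso-Seq, also holds counts and RPKM, with totals between 47382149 and 63497688 reads per library. The deposited Iso-Seq table gives transcript length in bases, per the file headers, and no expression. Of the gene lengths 99.6% are multiples of 3, so they were read as coding lengths. Gene identifiers are those of the TGACv1 annotation of Chinese Spring, and 99.0% of the genes carry a protein description. Gene positions were not used here, because the reference annotation at hand has other identifiers.

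Library totals over genes, for replicates 1, 2 and 3, were 21511580, 20764889 and 20848102 in 14 DPA embryo, 20631406, 19963721 and 20068924 in 25 DPA embryo, 17914215, 18517070 and 19415755 in 14 DPA endosperm and 17923630, 18751246 and 18567461 in 25 DPA endosperm reads. Values from a few reads are imprecise, and a gene with no read in a group was set to a floor of 3 counts per library for a lower bound of its fold change. Where a group held 1 to 3 reads of a gene, levels are given in place of a fold. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic.

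Gene comparisons used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with all 12 libraries in 1 fit of 4 groups and TMM scaling. Genes with an RPKM of 1 or more in at least 3 libraries were tested, 51236 in all. The comparisons were embryo against endosperm at each stage, 25 against 14 DPA in each tissue, and the interaction of tissue and stage. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of 1 or more. Replicate numbers do not pair the libraries: of 18 pairs with the same number, 1 had a correlation of residuals over 0.1 (median 0.0073, against -0.0029 for different numbers). No replicate term was used, and a term for replicate is among the alternatives. The chi-square per gene between replicates was at least 2.64, so no pair of libraries was identical.

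The gene lists were fixed as word patterns on the protein descriptions before the data were examined, as were the comparisons, the thresholds, the rule for naming genes and most of the other settings. They cover prolamins, starch synthesis, grain defence and inhibitors, oil body proteins, globulins, late embryogenesis abundant proteins, heat shock proteins, core histones, DNA replication, the cell cycle, photosynthesis, flavonoids, ribosomal proteins, abscisic acid, auxin, gibberellin, embryo patterning factors, sucrose supply, protein folding in the endoplasmic reticulum, cell wall growth, redox protection, and cell death with protein breakdown, 22 lists. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation, adjusted over the lists within a comparison. With the estimated correlation 2, 4, 1, 1 and 2 lists were called in the 5 comparisons in the order above.

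Homoeolog sets were planned to follow the deposited single-copy table, but that table does not group homoeologs. Sets were therefore built as genes that share the best protein database hit and the chromosome group, with exactly 1 gene on each of A, B and D, giving 8504 sets, a definition chosen after the tables were opened. The log2 ratio of deposited RPKM, with 0.1 RPKM added to each, was tested with limma within groups and between groups, for sets with a summed RPKM of 1 or more. A set was called when any of its 3 ratios had an adjusted p below 0.05 and an absolute value, or difference, of 1 or more. Such a fold change understates the change of weakly expressed homoeologs. Each set was also assigned to the nearest of 7 ideal patterns. Shares of prolamins and of subgenomes, and the number of genes at 1 RPKM or more, were compared by two-sided exact permutation tests.

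The rule for naming genes took, per comparison, the 5 largest changes in each direction among called genes with a known protein, 10 RPKM or more in the higher group and no overlap of replicates. It also took the 3 most abundant members of each list, and homoeolog sets by the same kind of limits. It gave 109 genes, of which the text names 67, chosen after their values were seen, so the named genes are a selection.

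The procedure was tested on simulated data, with 200 of 51236 genes changed. Changes of 4-fold were recovered in 97 to 99% of cases, with 2 to 8 false calls per comparison. Changes of 2-fold were scored by adjusted p alone, without the fold limit, and 40 to 50% were recovered. Their recovery by the full calling rule is not given. For embryo homoeolog ratios recovery, not split by level, was 100% for 4-fold and, without the fold limit, 81% for 2-fold, with 7 false calls. The interaction was not tested in this way. Alternatives were DESeq2 1.42.0 and its size factors, other filters, thresholds and prior counts, scaling without storage and defence genes, each library left out in turn, and fits of the 6 libraries compared. DESeq2 gave no adjusted p for 3 genes per comparison, which were left out of its counts. Added after the data were seen were counts without scaling beyond total reads, without endosperm replicates 2 and 3 at 14 DPA, from non-redundant transcripts, with a prior count of 0.01, and for homoeologs with coding lengths within 1.2 times or without group 1 sets that hold a short-arm gene. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.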

Results

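Grain transcripts were measured by paired-end RNA sequencing in the field-grown bread wheat cultivar Zhou 8425B. Bread wheat is a hexaploid with the subgenomes A, B and D, so many genes exist as 3 homoeologs. The embryo and the endosperm, the latter sampled together with the seed coat (episperm) and the fruit wall (pericarp), were taken at 14 and 25 days post anthesis (DPA). There were 3 biological replicates in each of the 4 groups, 12 libraries in all. In these libraries between 61974 and 69993 genes had a read, and 1 read in a gene of 1000 coding bases equals between 0.0465 and 0.0558 RPKM (reads per kilobase, relative to the library total). Levels are scaled RPKM, that is RPKM after TMM scaling between libraries, as mean ± SD with n = 3 libraries. Log2 fold changes come from edgeR and carry their standard error (SE). A gene was called at an adjusted p below 0.05 and an absolute log2 fold change of 1 or more. Each gene is named by its deposited protein description and its identifier, which holds the chromosome arm; positions were not used here.

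Prolamin transcripts held a large part of the endosperm libraries and little of the embryo libraries. Prolamins, the gliadins and glutenins that form gluten, held 24.9 ± 3.44% of the summed RPKM in endosperm at 14 DPA and 28.1 ± 2.60% at 25 DPA. In embryo they held 0.050 ± 0.00221% and 0.186 ± 0.0395% (SD, n = 3 each). The share was higher in each of 6 endosperm libraries than in any of 6 embryo libraries (two-sided exact permutation test over both stages, p = 0.0022). Between the endosperm stages the difference was 3.16 points (exact permutation p = 0.3), and it turned to -0.126 points without replicates 2 and 3 at 14 DPA. With 3 against 3 libraries the exact p cannot fall below 0.1. Genes at 1 RPKM or more numbered 44944 ± 89 in embryo at 14 DPA, 43186 ± 319 at 25 DPA, 40957 ± 3719 in endosperm at 14 DPA and 35903 ± 969 at 25 DPA. Over both stages embryo stood above endosperm by 5635 genes (exact permutation p = 0.0087, adjusted p = 0.043 over 5 comparisons). With RPKM scaled by median ratios between libraries the difference turned to -1896 genes (exact permutation p = 0.0022, adjusted p = 0.011 over 5 comparisons). Genes with any read differed by 694 (exact permutation p = 0.65), so the direction depends on the measure. At 14 DPA the difference in genes listed at 1 RPKM or more, embryo 14 DPA minus endosperm 14 DPA, was 3986, 1907 without endosperm replicate 1 and 8146 without endosperm 14 DPA replicates 2 and 3.

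The 3 endosperm libraries at 14 DPA differed from each other in their embryo transcripts. A set of 83 genes had at least 20 scaled RPKM in embryo at 14 DPA and at most 1% of that level in every endosperm library at 25 DPA. In endosperm replicates 1, 2 and 3 at 14 DPA their median level was 0.611, 36.2 and 54.2% of the embryo level. In the 25 DPA endosperm libraries it was 0, 0.158 and 0.291%. A set of 321 endosperm genes, at 1% or less in all embryo libraries, stood in the same replicates at 106, 64.8 and 44.9% of the 25 DPA endosperm level. The number of genes called for tissue at 14 DPA and stage in endosperm is therefore also given without 14 DPA endosperm replicates 2 and 3. This second count was chosen after the values were seen, and its lone library is assumed to vary like the other groups.

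**Figure D1:**
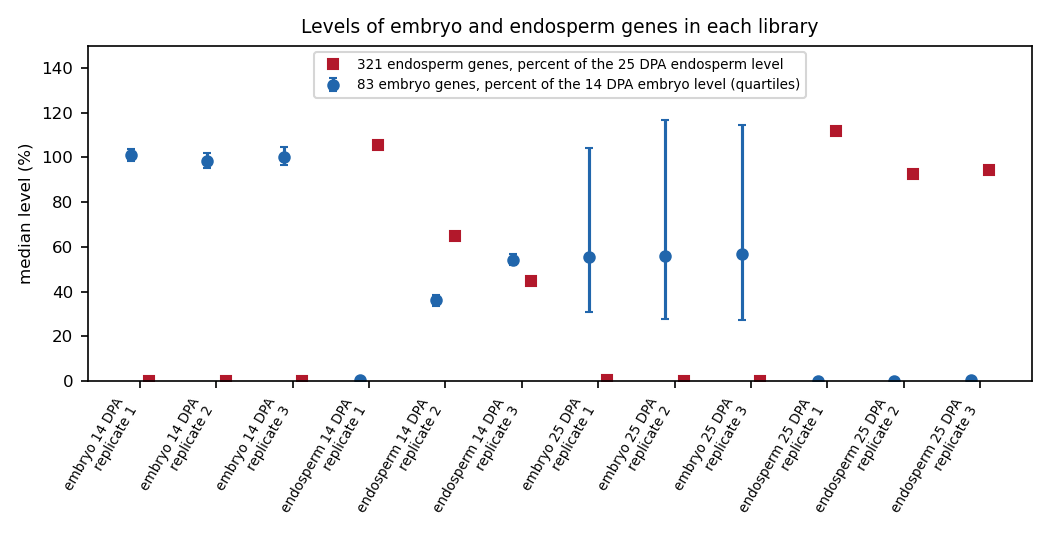
Median level of 83 embryo genes, as percent of the 14 DPA embryo level with quartiles, and of 321 endosperm genes, as percent of the 25 DPA endosperm level, in each library. In the 14 DPA endosperm replicates 1, 2 and 3 the embryo genes stand at 0.611, 36.2 and 54.2% and the endosperm genes at 106, 64.8 and 44.9%.

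The first comparison asked which genes separate embryo from endosperm at 14 DPA. Among the genes lower in embryo were gliadins, which store nitrogen for the seedling. An alpha-gliadin (TRIAE_CS42_U_TGACv1_665230_AA2153870) measured 32.7 ± 2.23 scaled RPKM in embryo and 47285 ± 17923 in endosperm, a log2 fold change of -10.50 (SE 0.50). A gamma gliadin (TRIAE_CS42_1DS_TGACv1_080991_AA0256470) differed by -10.12 (SE 0.38). The membrane-active defence peptides alpha and beta purothionin (TRIAE_CS42_1BL_TGACv1_034203_AA0143760 and TRIAE_CS42_1AL_TGACv1_001544_AA0031990) differed by -10.58 (SE 0.41) and -10.50 (SE 0.38). A PR60 precursor of transfer cells, which carry nutrients into the endosperm, had no read in embryo (TRIAE_CS42_1AS_TGACv1_019084_AA0060370) and was at least 728-fold lower there, against a floor of 3 counts per library. A second PR60 gene (TRIAE_CS42_5BL_TGACv1_408087_AA1361570) differed by -12.22 (SE 0.75) and a cellulase (TRIAE_CS42_6AS_TGACv1_485269_AA1542140), which cleaves cell wall glucan, by -12.32 (SE 0.56). A gene described as RUPTURED POLLEN GRAIN 1 (TRIAE_CS42_U_TGACv1_641589_AA2098880) was at least 324-fold lower in embryo. The oxygenase SRG1 (TRIAE_CS42_6DS_TGACv1_542917_AA1732540) stood at 0.0192 ± 0.0332 in embryo and 128 ± 57.3 in endosperm. Floors cover counting error only, and SEs the spread in all 4 groups, compared or not.

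Counts per gene list are given as higher and lower in embryo, with the counts adjusted over the list alone in brackets. Prolamin genes had 0 higher and 42 lower of 42 (0 and 42 adjusted over the list alone), at a median log2 fold change of -10.11, unchanged to 2 decimals with 4 genes at their bound (camera adjusted p = 3.2e-116, adjusted p = 0.017 with an estimated correlation). Photosynthesis genes, markers of green pericarp, had 1 higher and 101 lower of 106 (1 and 101) at a median of -5.95, or -5.69 with 11 genes at their bound (camera adjusted p = 1.5e-23, adjusted p = 0.21 with an estimated correlation). The photosystem II 10 kDa protein (TRIAE_CS42_6DL_TGACv1_528220_AA1712590) differed by -6.64 (SE 0.53). Grain defence and inhibitor genes had 12 higher and 65 lower of 136 (18 and 66), and their median of -0.87 turned to 0.0279 without scaling beyond total reads (camera adjusted p = 6.2e-18, adjusted p = 0.017 with an estimated correlation). The higher count was 7 or 7 without embryo replicate 2 or 3 and 23 without endosperm replicate 3. Sucrose supply genes had 6 higher and 39 lower of 70 (6 and 39, camera adjusted p = 4.3e-09, adjusted p = 0.11 with an estimated correlation). Abscisic acid genes had 5 higher and 23 lower of 44 (5 and 23, camera adjusted p = 4.6e-04, adjusted p = 0.11 with an estimated correlation). The dormancy regulator VIVIPAROUS1 (TRIAE_CS42_3B_TGACv1_224932_AA0803240) was higher in embryo by 1.18 (SE 0.30), a call that ended without endosperm replicate 1 (0.86). Gibberellin genes had 4 higher and 9 lower of 17 (5 and 9, camera adjusted p = 0.013, adjusted p = 0.11 with an estimated correlation), with Gibberellin 20 oxidase 1 (TRIAE_CS42_4AL_TGACv1_289001_AA0963150), an enzyme of gibberellin synthesis, at -6.29 (SE 0.43). The boundary regulator CUP-SHAPED COTYLEDON 2 (TRIAE_CS42_5AL_TGACv1_377157_AA1244560) stood at 0.242 ± 0.0786 in embryo and 295 ± 132 in endosperm. Its list, embryo patterning factors, had 28 higher and 30 lower of 90 (31 and 32). The median of that list was 0.26, opposite in sign to its test (camera adjusted p = 0.034, adjusted p = 0.21 with an estimated correlation). Its higher count was 14, 13 or 14 without embryo replicate 1, 2 or 3 and 15 without endosperm replicate 2. Without endosperm replicates 2 and 3 the counts higher and lower were 0 and 42 for prolamins, 1 and 101 for photosynthesis, 25 and 67 for defence, 11 and 39 for sucrose supply, 7 and 25 for abscisic acid, 6 and 9 for gibberellin and 41 and 33 for patterning.

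Dividing tissue makes histones and replication proteins. Core histones, which package newly made DNA, had 94 higher and 8 lower of 236 (100 and 8, camera adjusted p = 9.7e-10, adjusted p = 0.21 with an estimated correlation). DNA replication genes had 24 higher and 1 lower of 56 (25 and 1, camera adjusted p = 5.3e-06, adjusted p = 0.28 with an estimated correlation), cell cycle genes 25 higher and 0 lower of 48 (25 and 0, camera adjusted p = 1.5e-05, adjusted p = 0.28 with an estimated correlation) and auxin genes 37 higher and 11 lower of 83 (39 and 11, camera adjusted p = 4.3e-04, adjusted p = 0.37 with an estimated correlation). The replication licensing factor MCM3 (TRIAE_CS42_1AL_TGACv1_000388_AA0010880) measured 25.1 ± 0.979 in embryo and 10.1 ± 6.76 in endosperm, a log2 fold change of 1.31 (SE 0.43). Its call ended without embryo replicate 1 (1.29) or 2 (1.29) and without endosperm replicate 1 (0.85). Late embryogenesis abundant genes, which protect drying tissue, had 22 higher and 6 lower of 54 (24 and 6, camera adjusted p = 0.0043, adjusted p = 0.4 with an estimated correlation). Dehydrin 1 (TRIAE_CS42_5BL_TGACv1_404666_AA1307790) differed by 1.52 (SE 0.45), the lipid-transfer protein DIR1 (TRIAE_CS42_4BL_TGACv1_320395_AA1037620) by 1.98 (SE 0.52), the GTPase ROP6 (TRIAE_CS42_1BL_TGACv1_030978_AA0104970) by 1.99 (SE 0.57) and wali2 (TRIAE_CS42_6BS_TGACv1_514413_AA1659410) by 2.04 (SE 0.59). In a fit of the 6 libraries alone the calls of MCM3, dehydrin 1, ROP6 and wali2 ended at log2 fold changes of 1.31, 1.52, 1.99 and 2.05, and that of wali2 also with DESeq2 (2.22). Without endosperm replicates 2 and 3, which held the embryo transcripts, the counts higher in embryo were 159 histones, 41 replication, 38 cell cycle, 57 auxin and 31 late embryogenesis genes. Histones numbered 44, 54 or 46 without embryo replicate 1, 2 or 3 and 51 without endosperm replicate 1. Replication genes numbered 11, 11 or 11 without embryo replicate 1, 2 or 3 and 8 or 14 without endosperm replicate 1 or 2, and cell cycle genes 11, 9 or 9 without embryo replicate 1, 2 or 3 and 12 without endosperm replicate 2. Auxin genes numbered 23 or 23 without embryo replicate 2 or 3 and 15 without endosperm replicate 1.

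The medians of 9 further lists were below 0 and turned positive without scaling beyond total reads. Starch synthesis genes had 19 higher and 33 lower of 77 (19 and 33), median -0.51 against 0.40 without scaling (camera adjusted p = 7.2e-05, adjusted p = 0.06 with an estimated correlation). Starch branching enzyme I (TRIAE_CS42_7AL_TGACv1_556597_AA1766600), which adds branch points to amylopectin, differed by -4.18 (SE 0.21). Cell death and protein breakdown genes had 25 higher and 82 lower of 203 (29 and 83), median -0.51 against 0.40 without scaling (camera adjusted p = 8.7e-05, adjusted p = 0.11 with an estimated correlation). Flavonoid genes had 13 higher and 37 lower of 82 (13 and 37), median -0.63 against 0.29 without scaling (camera adjusted p = 9.7e-04, adjusted p = 0.11 with an estimated correlation), and heat shock genes 9 higher and 37 lower of 110 (9 and 37), median -0.46 against 0.44 without scaling (camera adjusted p = 0.035, adjusted p = 0.52 with an estimated correlation). Cell wall growth genes had 29 higher and 62 lower of 181 (33 and 62), median -0.17 against 0.72 without scaling (camera adjusted p = 0.17, adjusted p = 0.21 with an estimated correlation), with the wall-loosening beta-expansin TaEXPB2 (TRIAE_CS42_1AL_TGACv1_002200_AA0039680) at -6.41 (SE 0.37). Redox genes had 16 higher and 47 lower of 137 (20 and 49), median -0.49 against 0.42 without scaling (camera adjusted p = 0.068, adjusted p = 0.44 with an estimated correlation), and genes of protein folding in the endoplasmic reticulum 2 higher and 10 lower of 47 (2 and 10), median -0.21 against 0.69 without scaling (camera adjusted p = 0.29, adjusted p = 0.57 with an estimated correlation). The folding enzyme protein disulfide isomerase 2 (TRIAE_CS42_4BS_TGACv1_328187_AA1084280) differed by -1.73 (SE 0.17), a call that ended without scaling (-0.80). Globulin genes had 2 higher and 5 lower of 19 (2 and 5), median -0.00682 against 0.89 without scaling (camera adjusted p = 0.11, adjusted p = 0.44 with an estimated correlation), and oil body genes 0 higher and 4 lower of 9 (0 and 4), median -0.48 against 0.43 without scaling (camera adjusted p = 0.32, adjusted p = 0.4 with an estimated correlation). Ribosomal protein genes had 18 higher and 21 lower of 507 (16 and 21) at a median of 0.27 (camera adjusted p = 1.9e-04, adjusted p = 0.21 with an estimated correlation). Without endosperm replicates 2 and 3 the counts were 24 and 34 for starch, 49 and 85 for cell death, 21 and 39 for flavonoids, 24 and 39 for heat shock, 58 and 66 for cell wall growth, 23 and 56 for redox, 7 and 11 for protein folding, 9 and 5 for globulins, 2 and 4 for oil bodies and 86 and 26 for ribosomal proteins. Counts higher in embryo moved with single libraries. For starch there were 12 without embryo replicate 2 and 7 without endosperm replicate 1, for flavonoids 8, 6 or 7 without embryo replicate 1, 2 or 3 and 8 or 7 without endosperm replicate 1 or 2, and for cell death 14, 13 or 14 without embryo replicate 1, 2 or 3 and 15 or 39 without endosperm replicate 1 or 3. For cell wall growth there were 16, 16 or 13 without embryo replicate 1, 2 or 3 and 19 or 46 without endosperm replicate 2 or 3, for redox 10 without embryo replicate 1, for heat shock 16 without endosperm replicate 3 and for ribosomal proteins 6 or 30 without endosperm replicate 1 or 3.

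In all, 17186 of 51236 genes were called at 14 DPA, 5691 higher and 11495 lower in embryo, around a median of all genes of 0.029. Without scaling beyond total reads 75.9% of the calls were higher, against 33.1%, around a median of 0.91. The higher count was 3689, 3592 or 3499 without embryo replicate 1, 2 or 3, 3189 without endosperm replicate 1 and 9258 without endosperm replicate 3. In a fit of the 6 libraries compared it was 3043, 21.4% of the calls, against 11170 lower. Without endosperm replicates 2 and 3 there were 26730 calls, 14119 higher and 12611 lower. The 21 genes named for this comparison were chosen among the called ones, with a highest adjusted p = 0.023 (edgeR). By their mean log2 level all 17 lists called by camera were apart in 3 of 3 embryo libraries, and so were the 5 lists not called, so this measure does not set the called lists off.

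**Figure D2:**
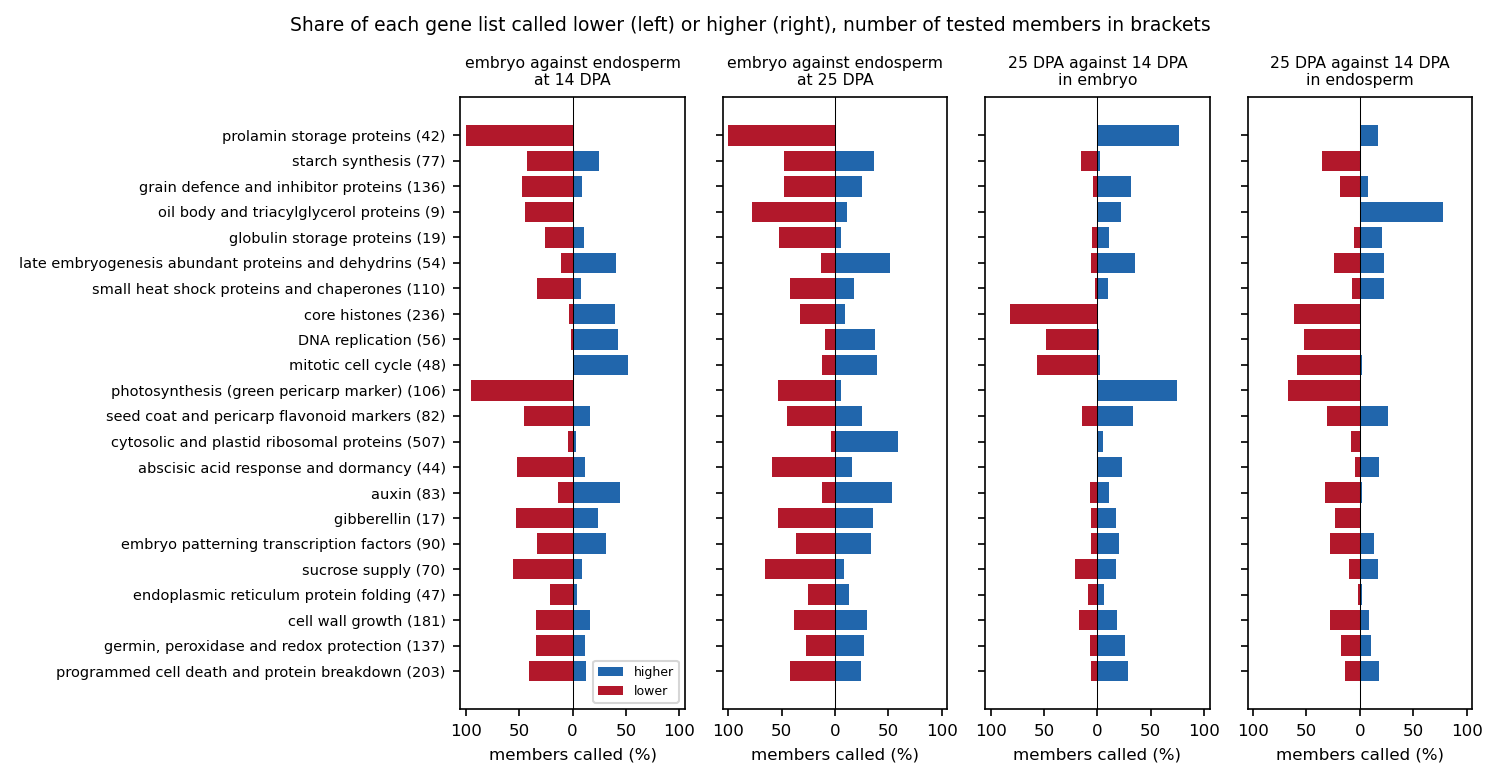
Share of each gene list called higher or lower in each comparison (percent of members tested, edgeR with TMM scaling). All 42 prolamin genes are lower in embryo at both stages, also without scaling, and 194 of 236 histone genes are lower at 25 than at 14 DPA in embryo, also without scaling.

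The same comparison was made at 25 DPA. Of the genes named by the size of their change, several had no read in one of the tissues. Lipoxygenase 3 (TRIAE_CS42_5DL_TGACv1_436636_AA1462370), which starts oxylipin synthesis, had no read in endosperm and was at least 213-fold higher in embryo, and an enzyme of benzoxazinoid defence compounds (TRIAE_CS42_2AL_TGACv1_094425_AA0297430), also without a read there, at least 113-fold. Indole synthase (TRIAE_CS42_4AS_TGACv1_306233_AA1004820), O-methyltransferase ZRP4 (TRIAE_CS42_1BL_TGACv1_031702_AA0119190) and a chitinase (TRIAE_CS42_3B_TGACv1_226118_AA0814050), which cleaves fungal wall chitin, had none either and were at least 90.5-fold, 84.6-fold and 95.3-fold higher. A pair of Em genes of late embryogenesis (TRIAE_CS42_1AL_TGACv1_002164_AA0039330 and TRIAE_CS42_1BL_TGACv1_031805_AA0120890) differed by 8.61 (SE 1.18) and 6.24 (SE 0.96), the first at 2589.6 ± 88.6 in embryo and 6.58 ± 0.598 in endosperm. Heat shock protein 90 (TRIAE_CS42_5DL_TGACv1_434138_AA1430290) differed by 3.21 (SE 0.41), against its list's median but not summed level, and wali2 (TRIAE_CS42_6BS_TGACv1_514413_AA1659410) by 8.07 (SE 0.98). A defensin (TRIAE_CS42_7BL_TGACv1_576933_AA1860390), a small antifungal protein, stood at 219 ± 27.9 in embryo and 0.224 ± 0.194 in endosperm. Formate dehydrogenase (TRIAE_CS42_4DS_TGACv1_361511_AA1169370) and a polygalacturonase (TRIAE_CS42_5DL_TGACv1_434588_AA1438370), which cleaves pectin, were lower in embryo, at -10.24 (SE 0.63) and -10.21 (SE 0.40). The trypsin inhibitor CMe (TRIAE_CS42_4AL_TGACv1_291306_AA0993650), a phosphotransfer protein (TRIAE_CS42_4DS_TGACv1_360999_AA1158020) and SRG1 (TRIAE_CS42_5AL_TGACv1_374512_AA1202090) had no read in embryo and were at least 108-fold, 89.3-fold and 175-fold lower.

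Ribosomal protein genes had 298 higher and 18 lower of 507 (299 and 18) at a median of 1.23 (camera adjusted p = 2.2e-23, adjusted p = 0.03 with an estimated correlation). The subunits S8 (TRIAE_CS42_2BL_TGACv1_129494_AA0386090) and L27-3 (TRIAE_CS42_7BL_TGACv1_581229_AA1916770) differed by 1.59 (SE 0.14) and 1.12 (SE 0.13). Auxin genes had 44 higher and 10 lower of 83 (44 and 10, camera adjusted p = 6.7e-04, adjusted p = 0.47 with an estimated correlation). Prolamin genes had 0 higher and 42 lower of 42 (0 and 42) at a median of -8.49 (camera adjusted p = 1.0e-75, adjusted p = 0.03 with an estimated correlation), with the gamma gliadin TRIAE_CS42_1DS_TGACv1_080991_AA0256470 at -8.47 (SE 0.36). Oil body genes had 1 higher and 7 lower of 9 (1 and 7, camera adjusted p = 0.0021, adjusted p = 0.045 with an estimated correlation). Defence genes had 34 higher and 65 lower of 136 (34 and 65, camera adjusted p = 4.0e-09, adjusted p = 0.03 with an estimated correlation), and their median of -0.96, or -0.89 with 11 genes at their bound, turned to 0.0986 without scaling. Alpha and beta purothionin (TRIAE_CS42_1BL_TGACv1_034203_AA0143760 and TRIAE_CS42_1AL_TGACv1_001544_AA0031990) differed by -9.27 (SE 0.39) and -9.06 (SE 0.36). Globulin genes, storage proteins of embryo and outer endosperm, had 1 higher and 10 lower of 19 (1 and 10), median -1.08 against 0.0174 without scaling (camera adjusted p = 0.0038, adjusted p = 0.23 with an estimated correlation). Globulin-3A (TRIAE_CS42_4AL_TGACv1_290346_AA0984300) differed by -1.22 (SE 0.22), a call that ended without scaling (-0.13). Starch synthesis genes had 28 higher and 37 lower of 77 (28 and 37), median -0.72 against 0.38 without scaling (camera adjusted p = 7.7e-04, adjusted p = 0.052 with an estimated correlation). Starch branching enzyme I (TRIAE_CS42_7AL_TGACv1_556597_AA1766600) differed by -5.43 (SE 0.23), and the large subunit of ADP-glucose pyrophosphorylase (TRIAE_CS42_1AL_TGACv1_000939_AA0022300), which makes the starch precursor, by -2.72 (SE 0.21). Sucrose supply genes had 6 higher and 46 lower of 70 (7 and 46, camera adjusted p = 1.1e-10, adjusted p = 0.052 with an estimated correlation), and TaEXPB2 (TRIAE_CS42_1AL_TGACv1_002200_AA0039680) differed by -5.05 (SE 0.34). Abscisic acid genes had 7 higher and 26 lower of 44 (7 and 26, camera adjusted p = 1.6e-04, adjusted p = 0.052 with an estimated correlation), with VIVIPAROUS1 (TRIAE_CS42_3B_TGACv1_224932_AA0803240) again higher in embryo, by 1.29 (SE 0.30). Core histones had 22 higher and 78 lower of 236 (21 and 75), with 66 higher and 41 lower without scaling, and were not called as a list (camera adjusted p = 0.14, adjusted p = 0.75 with an estimated correlation).

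Heat shock and chaperone genes had 20 higher and 46 lower of 110 (20 and 46), median -0.65 against 0.45 without scaling (camera adjusted p = 0.0060, adjusted p = 0.52 with an estimated correlation). Cell death and protein breakdown genes had 50 higher and 85 lower of 203 (50 and 85), median -0.59 against 0.51 without scaling (camera adjusted p = 0.0038, adjusted p = 0.14 with an estimated correlation). Embryo patterning factors, called lower as a list at a median of 0.0618, had 30 higher and 33 lower of 90 (30 and 33, camera adjusted p = 0.026, adjusted p = 0.25 with an estimated correlation) and gibberellin genes 6 higher and 9 lower of 17 (6 and 9, camera adjusted p = 0.036, adjusted p = 0.12 with an estimated correlation). Late embryogenesis genes had 28 higher and 7 lower of 54 (28 and 7, camera adjusted p = 0.025, adjusted p = 0.56 with an estimated correlation) and DNA replication genes 21 higher and 5 lower of 56 (21 and 4, camera adjusted p = 0.036, adjusted p = 0.66 with an estimated correlation).

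In all, 25455 genes were called at 25 DPA, 12891 higher and 12564 lower in embryo, around a median of all genes of 0.11. Without scaling beyond total reads 79.8% of the calls were higher, against 50.6%, around a median of 1.21. The 25 genes named among the called ones had a highest adjusted p = 0.0021. Of 16 lists called, 15 were apart in 3 of 3 embryo libraries, as were 5 of 6 not called; photosynthesis genes, with 6 higher and 57 lower of 106 (6 and 57, camera adjusted p = 0.0058, adjusted p = 0.68 with an estimated correlation), were apart in 2. Photosynthesis genes higher in embryo numbered 10 without 14 DPA endosperm replicate 1 and 15 without 25 DPA embryo replicate 1.

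The third comparison followed the embryo from 14 to 25 DPA. Histone transcripts fell. A histone H4 gene (TRIAE_CS42_1BL_TGACv1_031587_AA0116540) went from 38.1 ± 2.61 to no read and was at least 98.6-fold lower, and histone H2B.10 (TRIAE_CS42_3DS_TGACv1_273777_AA0933410) was at least 91.6-fold lower. Core histones had 1 higher and 194 lower of 236 (1 and 198) at a median of -4.18, or -3.32 with 40 genes at their bound (camera adjusted p = 2.2e-91, adjusted p = 0.027 with an estimated correlation). DNA replication genes had 1 higher and 27 lower of 56 (2 and 28, camera adjusted p = 1.7e-13, adjusted p = 0.18 with an estimated correlation) and cell cycle genes 1 higher and 27 lower of 48 (1 and 27, camera adjusted p = 1.2e-13, adjusted p = 0.18 with an estimated correlation), with MCM3 (TRIAE_CS42_1AL_TGACv1_000388_AA0010880) at -2.82 (SE 0.45). High mobility group B protein 7 (TRIAE_CS42_7AL_TGACv1_558227_AA1791320), which bends DNA, and Pyruvate decarboxylase isozyme 1 (TRIAE_CS42_3AS_TGACv1_213543_AA0707220), an enzyme of fermentation, were at least 114-fold and 89.4-fold lower. Sucrose synthase 2 (TRIAE_CS42_2AS_TGACv1_112101_AA0330380), which splits sucrose, fell from 111 ± 0.573 to 0.361 ± 0.174, a log2 fold change of -8.26 (SE 0.55).

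Prolamin genes had 32 higher and 0 lower of 42 (32 and 0) at a median of 1.99, or 1.92 with 4 genes at their bound (camera adjusted p = 5.6e-18, adjusted p = 0.21 with an estimated correlation). The gamma gliadin TRIAE_CS42_1DS_TGACv1_080991_AA0256470 rose from 34.0 ± 1.39 to 194 ± 20.2 (log2 2.51, SE 0.27), against 68828 ± 6071 in endosperm at 25 DPA. Photosynthesis genes had 79 higher and 0 lower of 106 (89 and 0, camera adjusted p = 2.1e-08, adjusted p = 0.47 with an estimated correlation), with TRIAE_CS42_6DL_TGACv1_528220_AA1712590 at 2.67 (SE 0.52). The risen photosynthesis genes numbered 52 without replicate 2 at 14 DPA and 39 or 46 without replicate 2 or 3 at 25 DPA. The 5 named genes with the largest rises were a pair of nuclease S1 genes (TRIAE_CS42_2AL_TGACv1_094134_AA0293160 and TRIAE_CS42_2BL_TGACv1_130259_AA0407500), which degrade nucleic acids in dying cells, at 5.52 (SE 0.48) and 5.09 (SE 0.41), heat shock protein 16.9 (TRIAE_CS42_3DS_TGACv1_272901_AA0926370) at 5.50 (SE 0.49), a reticuline oxidase-like gene (TRIAE_CS42_1AL_TGACv1_000845_AA0020270) at 4.71 (SE 0.32) and a blue copper protein gene (TRIAE_CS42_6DL_TGACv1_526956_AA1696010) at 4.99 (SE 0.54). Each was more abundant in endosperm at 25 DPA, where nuclease S1 (TRIAE_CS42_2AL_TGACv1_094134_AA0293160) measured 84.3 ± 22.4 against 10.7 ± 4.11 in embryo. Of all 5835 genes that rose, 3654 (62.6%) had a higher mean in endosperm at 25 DPA. Late embryogenesis genes had 19 higher and 3 lower of 54 (19 and 3, camera adjusted p = 7.7e-04, adjusted p = 0.44 with an estimated correlation) and defence genes 43 higher and 5 lower of 136 (45 and 5, camera adjusted p = 4.4e-04, adjusted p = 0.18 with an estimated correlation). Cell death genes had 59 higher and 12 lower of 203 (63 and 15, camera adjusted p = 3.3e-04, adjusted p = 0.17 with an estimated correlation), and those that fell numbered 19 or 19 without endosperm replicate 1 or 3 at 14 DPA. Redox genes had 36 higher and 9 lower of 137 (38 and 10, camera adjusted p = 0.016, adjusted p = 0.37 with an estimated correlation) and ribosomal protein genes 28 higher and 2 lower of 507 (29 and 2) at a median of 0.44 (camera adjusted p = 2.4e-06, adjusted p = 0.18 with an estimated correlation). An abscisic acid-inducible protein kinase (TRIAE_CS42_2BL_TGACv1_129567_AA0388890) rose by 1.21 (SE 0.26). Cell wall growth genes had 33 higher and 32 lower of 181 (33 and 37) at a median of -0.26, and the list was called lower (camera adjusted p = 0.013, adjusted p = 0.16 with an estimated correlation). Its member EXPA9 (TRIAE_CS42_5BL_TGACv1_406965_AA1351930), a wall-loosening expansin, stood at 1.13 (SE 0.22), a call that ended without scaling (0.92), in a fit of the 6 libraries (0.97), with DESeq2 or its size factors (0.99 and 0.99) and without replicate 1 at 25 DPA (0.99). Starch synthesis genes had 2 higher and 12 lower of 77 (2 and 12, camera adjusted p = 6.2e-04, adjusted p = 0.14 with an estimated correlation), with starch branching enzyme I (TRIAE_CS42_7AL_TGACv1_556597_AA1766600) at -1.09 (SE 0.19).

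In all, 9839 genes were called between the embryo stages, 5835 higher and 4004 lower at 25 DPA, around a median of all genes of 0.18. The higher calls made up 59.3% with TMM scaling, 46.4% without scaling beyond total reads (median of all genes -0.0202) and 48.9% with the size factors of DESeq2. In a fit of the 6 embryo libraries there were 4875 higher and 5770 lower calls. The 16 genes named among the called ones had a highest adjusted p = 0.0031. All 12 lists called were apart in 3 of 3 libraries, as were 6 of 10 not called.

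The fourth comparison followed the endosperm sample from 14 to 25 DPA. The 5 largest rises named included 4 polygalacturonase genes, whose enzymes cleave pectin. Of these, TRIAE_CS42_5DL_TGACv1_434588_AA1438370 went from 0.658 ± 0.414 to 114 ± 13.7 (log2 7.52, SE 0.34), and TRIAE_CS42_5AL_TGACv1_376037_AA1231110 and TRIAE_CS42_5BL_TGACv1_405854_AA1336540 rose by 7.33 (SE 0.45) and 6.62 (SE 0.38). A further one, TRIAE_CS42_5BL_TGACv1_404837_AA1312380, stood at 0.0294 ± 0.0508 and 20.5 ± 1.31. Expansin-B7 (TRIAE_CS42_3DL_TGACv1_250163_AA0863360), a wall-loosening protein, rose by 6.30 (SE 0.46). Oil body genes, which coat lipid droplets, had 7 higher and 0 lower of 9 (7 and 0) at a median of 1.85 (camera adjusted p = 3.7e-10, adjusted p = 0.0031 with an estimated correlation), and 6 and 0 without replicates 2 and 3 at 14 DPA. A caleosin of that list (TRIAE_CS42_6BL_TGACv1_499952_AA1595740) stood at 1.34 (SE 0.17), a call that ended without scaling (0.96) and without replicates 2 and 3 at 14 DPA (0.94). Globulin-3A (TRIAE_CS42_4AL_TGACv1_290346_AA0984300) and globulin 3 (TRIAE_CS42_4DS_TGACv1_361174_AA1162580) stood at 1.16 (SE 0.22) and 1.38 (SE 0.21), calls that ended without scaling (0.76 and 0.99), the first also without replicates 2 and 3 at 14 DPA (0.97). The kinase TRIAE_CS42_2BL_TGACv1_129567_AA0388890 stood at 1.07 (SE 0.27), a call that ended without scaling (0.58), without replicate 1 at 14 DPA (0.77) and without replicate 3 at 25 DPA (0.91). In a fit of the 6 endosperm libraries alone the calls of globulin-3A and the kinase ended (1.15 and 1.08).

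Heat shock and chaperone genes had 25 higher and 8 lower of 110 (27 and 8), median 0.32 against -0.10 without scaling (camera adjusted p = 9.2e-04, adjusted p = 0.48 with an estimated correlation), and 11 and 2 without replicates 2 and 3 at 14 DPA. Those lower numbered 15 without replicate 1 at 14 DPA. Cell death genes had 37 higher and 28 lower of 203 (37 and 30), median 0.25 against -0.16 without scaling (camera adjusted p = 0.0023, adjusted p = 0.23 with an estimated correlation), and 25 and 11 without the 2 libraries. Globulin genes had 4 higher and 1 lower of 19 (4 and 1), median 0.37 against -0.0794 without scaling (camera adjusted p = 0.022, adjusted p = 0.48 with an estimated correlation), and abscisic acid genes 8 higher and 2 lower of 44 (8 and 3), median 0.25 against -0.13 without scaling (camera adjusted p = 0.022, adjusted p = 0.34 with an estimated correlation). Without the 2 libraries they had 4 and 2, and 5 and 1.

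Photosynthesis genes had 0 higher and 71 lower of 106 (2 and 80) at a median of -1.80, or -1.76 with 4 genes at their bound (camera adjusted p = 3.8e-12, adjusted p = 0.48 with an estimated correlation), and 1 and 84 without replicates 2 and 3 at 14 DPA. Those that fell numbered 26 or 29 without replicate 2 or 3 at 25 DPA. Their summed scaled RPKM was uneven within each stage, at 3814, 2268 and 1588 in replicates 1, 2 and 3 at 14 DPA and 1764, 651 and 734 at 25 DPA. Over all genes replicate 1 at 25 DPA also stood apart, with a chi-square per gene of 18.2 and 20.8 against replicates 2 and 3, and 4.03 between those. At 14 DPA the photosynthesis sums fell from replicate 1 to 3 as the 321 endosperm genes did. Those genes stood at 106, 64.8 and 44.9% of their 25 DPA endosperm level. The spread at 14 DPA thus went with the embryo transcripts of replicates 2 and 3. An uneven share of green pericarp between libraries, mainly at 25 DPA, is not separated from the fall. The small subunit of the carbon-fixing enzyme RuBisCO (TRIAE_CS42_5AL_TGACv1_374932_AA1212330) stood at -1.41 (SE 0.40), a call that ended without replicate 2 or 3 at 25 DPA (-1.19 and -1.27). The cellulase TRIAE_CS42_6AS_TGACv1_485269_AA1542140 and the transfer cell gene TRIAE_CS42_5BL_TGACv1_408087_AA1361570 fell by 3.30 (SE 0.33) and 2.24 (SE 0.43) on the log2 scale, the second not called by DESeq2, and sucrose synthase 2 (TRIAE_CS42_2AS_TGACv1_112101_AA0330380) fell by 2.73 (SE 0.42). Starch synthesis genes had 0 higher and 27 lower of 77 (0 and 28, camera adjusted p = 7.1e-04, adjusted p = 0.11 with an estimated correlation), and 4 and 15 without the 2 libraries. Ribosomal protein genes had 1 higher and 43 lower of 507 (1 and 46, camera adjusted p = 7.5e-15, adjusted p = 0.086 with an estimated correlation), and those lower numbered 66 without replicate 1 at 14 DPA, 42 without the 2 libraries and 194 without scaling. Core histones had 0 higher and 145 lower of 236 (1 and 158) at a median of -2.33, or -1.91 with 23 genes at their bound (camera adjusted p = 5.0e-24, adjusted p = 0.23 with an estimated correlation), and 1 and 67 without the 2 libraries.

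Several gene groups moved with the 14 DPA endosperm libraries that held embryo transcripts. DNA replication genes had 0 higher and 29 lower of 56 (0 and 29, camera adjusted p = 3.3e-07, adjusted p = 0.48 with an estimated correlation) and cell cycle genes 1 higher and 28 lower of 48 (1 and 31, camera adjusted p = 1.6e-05, adjusted p = 0.48 with an estimated correlation). Without replicates 2 and 3 at 14 DPA they had 2 and 8, and 2 and 2. The replication genes that fell numbered 17 without replicate 3 at 14 DPA and 19 or 19 without replicate 1 or 3 at 25 DPA, and the cell cycle genes 17 without replicate 3 at 14 DPA and 15 or 18 without replicate 2 or 3 at 25 DPA. Late embryogenesis genes had 12 higher and 13 lower of 54 (12 and 14) with all libraries, at a median of 0.40 that turned to -0.0727 without scaling (camera adjusted p = 7.1e-04, adjusted p = 0.48 with an estimated correlation), and 20 and 0 without the 2. Those that fell numbered 8 without replicate 3 at 14 DPA and 8 without replicate 2 at 25 DPA. Auxin genes had 2 higher and 27 lower of 83 (2 and 28, camera adjusted p = 0.019, adjusted p = 0.67 with an estimated correlation), and 11 and 4 without the 2. Prolamin genes had 7 higher and 0 lower of 42 (7 and 0, camera adjusted p = 4.1e-05, adjusted p = 0.56 with an estimated correlation), with 17 without replicate 1 at 14 DPA and 0 without replicates 2 and 3. Peroxidase 12 (TRIAE_CS42_3AL_TGACv1_195509_AA0650360) measured 2.20, 95.2 and 142 in replicates 1, 2 and 3 at 14 DPA and 0.424 ± 0.0983 at 25 DPA (log2 -7.54, SE 1.15, -2.41 without the 2). A leaf thionin (TRIAE_CS42_5AL_TGACv1_385761_AA1258480) went from 52.3 ± 43.1 to 0.159 ± 0.276. An endo-xylanase (TRIAE_CS42_4AS_TGACv1_306686_AA1012040), a phytosulfokine receptor (TRIAE_CS42_5BL_TGACv1_404270_AA1293200) and a defensin (TRIAE_CS42_7BL_TGACv1_576933_AA1860390) stood at 12.4 ± 11.3, 19.7 ± 18.8 and 62.9 ± 58.5 at 14 DPA and at 0.0334, 0.0218 and 0.224 at 25 DPA, calls that ended without the 2 libraries.

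In all, 9941 genes were called between the endosperm stages, 3619 higher and 6322 lower at 25 DPA, around a median of all genes of -0.0823. Without replicates 2 and 3 at 14 DPA there were 6046, 3234 higher and 2812 lower, and 3602 genes were called in the same direction both ways. Without scaling beyond total reads 14.6% of the calls were higher, against 36.4%, around a median of -0.50. In a fit of the 6 endosperm libraries there were 2677 higher and 2559 lower calls (51.1% higher), so the excess of lower calls depends on the fit. The 18 genes named among the called ones had a highest adjusted p = 0.017. Of 14 lists called, 9 were apart in 3 of 3 libraries, as were 3 of 8 not called; prolamin, auxin and cell death genes were apart in 1, cell cycle genes in 2 and late embryogenesis genes in 0.

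The interaction of tissue and stage tested whether the change from 14 to 25 DPA differed between embryo and endosperm. Ribosomal protein genes moved up in embryo relative to endosperm, with 208 higher and 0 lower of 507 (225 and 0) at a median of 1.0 (camera adjusted p = 1.2e-32, adjusted p = 0.015 with an estimated correlation), and 134 and 1 without the 2 endosperm libraries. Subunit S8 (TRIAE_CS42_2BL_TGACv1_129494_AA0386090) went from 465 to 682 in embryo and from 361 to 226 in endosperm, a difference of 1.23 (SE 0.20), not called without the 2 libraries (0.89). Photosynthesis genes had 90 higher and 0 lower of 106 (92 and 0) at a median of 4.08 (camera adjusted p = 4.4e-34, adjusted p = 0.2 with an estimated correlation). A chlorophyll a-b binding protein (TRIAE_CS42_5DL_TGACv1_437406_AA1466150) went from 0.0134 to 3.36 ± 2.76 in embryo and from 24.1 ± 10.1 to 2.93 ± 2.68 in endosperm, and the RuBisCO small subunit (TRIAE_CS42_5AL_TGACv1_374932_AA1212330) differed by 3.22 (SE 0.59). Core histones had 2 higher and 78 lower of 236 (2 and 87) at a median of -1.63 (camera adjusted p = 3.0e-27, adjusted p = 0.14 with an estimated correlation), and 2 and 118 without the 2 libraries. Without 14 DPA endosperm replicate 1 the histones higher numbered 10. Histone H2A.2.1 (TRIAE_CS42_1AS_TGACv1_019041_AA0058780) dropped from 177 ± 17.3 to 0.403 ± 0.212 in embryo and stood at 90.1 ± 24.6 and 95.1 ± 6.35 in endosperm, a difference of -8.81 (SE 0.38). The histones H4 (TRIAE_CS42_1BL_TGACv1_031587_AA0116540 and TRIAE_CS42_1DL_TGACv1_062138_AA0209250), H2A.6 (TRIAE_CS42_5DL_TGACv1_435148_AA1446720) and H2B.2 (TRIAE_CS42_6DS_TGACv1_543122_AA1735730) had no read in embryo at 25 DPA and 2.96, 1.85, 0.972 and 1.75 scaled RPKM in endosperm.

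Prolamin genes had 27 higher and 0 lower of 42 (31 and 0, camera adjusted p = 1.3e-09, adjusted p = 0.42 with an estimated correlation), and 34 and 0 without the 2 libraries. Their count was 16 or 15 without 14 DPA embryo replicate 1 or 2 and 17 or 17 without 25 DPA endosperm replicate 2 or 3. Defence genes had 45 higher and 3 lower of 136 (55 and 3, camera adjusted p = 1.3e-04, adjusted p = 0.14 with an estimated correlation), and those higher numbered 27 or 28 without 14 DPA embryo replicate 1 or 2. Lipoxygenase 3 (TRIAE_CS42_5DL_TGACv1_436636_AA1462370), the benzoxazinoid enzyme TRIAE_CS42_2AL_TGACv1_094425_AA0297430 and the chitinase TRIAE_CS42_3B_TGACv1_226118_AA0814050 measured 17.1, 9.63 and 10.3 scaled RPKM in embryo at 14 DPA and 21.8, 17.7 and 26.4 at 25 DPA, where endosperm had no read. In 14 DPA endosperm replicates 1, 2 and 3, of which the last pair held embryo transcripts, they measured 0.129, 5.88 and 9.90, then 0.0990, 4.28 and 5.84, and 2.61, 2.997 and 5.53. Their fitted differences were 11.58 (SE 2.36), 10.87 (SE 2.04) and 10.64 (SE 1.14), and 6.11, 5.67 and 10.005 without the 2 libraries. With no read in endosperm at 25 DPA these sizes depend on the prior count and are not measured. In 14 DPA replicate 1 the first 2 genes stood near or below their floors (0.102 and 0.157), so their endosperm falls are not bounded. Indole synthase (TRIAE_CS42_4AS_TGACv1_306233_AA1004820) measured 0, 5.41 and 5.54 in 14 DPA endosperm, had no read at 25 DPA, and was not called without the 2 libraries. The leaf thionin TRIAE_CS42_5AL_TGACv1_385761_AA1258480 measured 154 and 179.9 in embryo and 52.3 and 0.159 in endosperm. Oil body genes had 0 higher and 3 lower of 9 (0 and 3, camera adjusted p = 6.0e-04, adjusted p = 0.049 with an estimated correlation). Sucrose synthase 2 (TRIAE_CS42_2AS_TGACv1_112101_AA0330380) and the ADP-glucose pyrophosphorylase subunit TRIAE_CS42_1AL_TGACv1_000939_AA0022300 differed by -5.53 (SE 0.63) and -1.69 (SE 0.28), and EXPA9 (TRIAE_CS42_5BL_TGACv1_406965_AA1351930) by 1.80 (SE 0.33), not called without the 2 libraries (0.98). Replication and cell cycle genes had 2 higher and 5 lower of 56 (2 and 5) and 3 higher and 5 lower of 48 (4 and 7) with all libraries, and 2 and 23, and 1 and 18, without the 2 (camera adjusted p = 0.0054, adjusted p = 0.65 with an estimated correlation for replication, camera adjusted p = 0.0058, adjusted p = 0.65 with an estimated correlation for the cell cycle). Without 14 DPA endosperm replicate 1 the higher counts of these lists were 11 and 13. Flavonoid genes had 19 higher and 2 lower of 82 (23 and 3, camera adjusted p = 0.0058, adjusted p = 0.14 with an estimated correlation), with 11 higher without 14 DPA embryo replicate 1, 12 without 25 DPA embryo replicate 2 and 11 without 25 DPA endosperm replicate 2. Redox genes had 30 higher and 1 lower of 137 (31 and 1, camera adjusted p = 0.0046, adjusted p = 0.35 with an estimated correlation), sucrose supply genes 3 higher and 11 lower of 70 (4 and 12, camera adjusted p = 0.0015, adjusted p = 0.35 with an estimated correlation) and globulin genes 2 higher and 4 lower of 19 (3 and 4, camera adjusted p = 0.013, adjusted p = 0.42 with an estimated correlation).

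In all, 6552 genes were called for the interaction, 4855 higher and 1697 lower, around a median of 0.31. The higher share was 74.1%, 84.9% without scaling (median 0.52) and 61.1% with the size factors of DESeq2. Without endosperm replicates 2 and 3 at 14 DPA the median of all genes turned to -0.0211. Without 14 DPA endosperm replicate 1 there were 11170 calls, 8660 of them higher. The higher count was 3216, 3081 or 3215 without 14 DPA embryo replicate 1, 2 or 3 and 3135 without 25 DPA embryo replicate 2. The 16 genes named among the called ones had a highest adjusted p = 0.0088.

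The series title names homoeolog expression bias, and 8504 sets with 1 gene on each of A, B and D were compared within each library. Levels here are deposited RPKM. The set of ribosomal protein L18-2 (TRIAE_CS42_1AS_TGACv1_019548_AA0067940, TRIAE_CS42_1BS_TGACv1_050644_AA0174140 and TRIAE_CS42_1DS_TGACv1_080150_AA0241520) had 459 ± 26.2, 0.111 ± 0.0964 and 164 ± 16.3 RPKM from A, B and D in 14 DPA embryo, a log2 ratio of A over B of 11.22 (SE 0.50). Its B gene lies on the short arm of 1B, where B held under 5% of the RPKM in 62.1% of the sets, so this ratio falls under what affects that arm. The chaperone HSC70-1 (TRIAE_CS42_4AL_TGACv1_288418_AA0948340 for A) was near silent from A, with 0.00961 ± 0.0166, 156 ± 5.48 and 254 ± 1.51 RPKM in the same group. The dehydrin DHN3 (TRIAE_CS42_6AL_TGACv1_473324_AA1530170 for A) had 0.0341 ± 0.0591, 241 ± 48.0 and 232 ± 54.4 RPKM in 25 DPA embryo, where A over D was -10.81 (SE 0.42). A papain-like cysteine proteinase (TRIAE_CS42_2BS_TGACv1_146230_AA0459590 for B) leaned to B, with 41.4 ± 1.97, 557 ± 17.5 and 184 ± 1.47 RPKM in 14 DPA embryo and 39.8 ± 3.12 from A and 285 ± 21.5 from B in 25 DPA endosperm. Globulin-1 S (TRIAE_CS42_5AL_TGACv1_374534_AA1202570 for A) leaned to A over B in all 4 groups, by 1.79 (SE 0.11) in 14 DPA embryo and 1.59 (SE 0.11) in 25 DPA endosperm. Gibberellin 20 oxidase 1 (TRIAE_CS42_4AL_TGACv1_289001_AA0963150 for A) exceeded its D homoeolog in endosperm by 1.37 (SE 0.23) at 14 DPA and 1.16 (SE 0.22) at 25 DPA. Ratios with a homoeolog near 0 depend on the added 0.1 RPKM.

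Biased sets, with a log2 ratio of 1 or more in any pair and adjusted p below 0.05 (limma), numbered 3134 of 7027 (44.6%) in 14 DPA embryo and 3641 of 6936 (52.5%) in 25 DPA embryo. In endosperm they numbered 3347 of 7052 (47.5%) and 3345 of 6258 (53.5%). B was the lower partner more often over all sets. Directions, patterns and subgenome shares were not computed without the 1B short-arm sets. Mapping effects on bias were not tested. In 14 DPA embryo A exceeded B in 1239 sets and B exceeded A in 836, and D exceeded B in 1189 and B exceeded D in 707. In 25 DPA endosperm these counts were 1297 and 969, and 1221 and 796. A exceeded D in 784 and D exceeded A in 860 sets of 14 DPA embryo. By the nearest of 7 ideal patterns 71.9, 66.8, 70.4 and 64.7% of the sets were balanced in 14 and 25 DPA embryo and in 14 and 25 DPA endosperm, and 11, 12.4, 11.8 and 12.3% had B suppressed. On the short arm of chromosome 1B, 146 of 235 sets (62.1%) had a B gene under 5% of the set's RPKM. On the other 40 chromosome arms the share of such near silent genes was 5.07% or less, with a median of 2.15%. Without the sets of group 1 that hold a short-arm gene, 2900 of 6795 sets were biased in 14 DPA embryo.

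**Figure D3:**
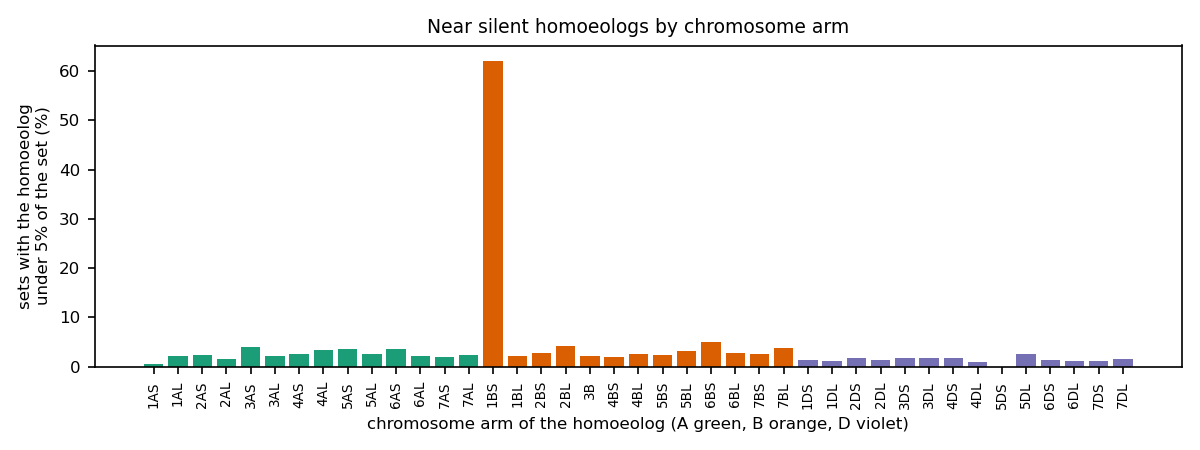
Percent of homoeolog sets in which the gene on the named chromosome arm holds under 5% of the set's RPKM, for 41 chromosome arms with at least 20 sets (3B as a whole). The short arm of 1B stands at 62.1% and every other arm at 5.07% or less.

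Starch branching enzyme IIb, an amylopectin enzyme, changed its leading copy. In 14 DPA embryo A, B and D (TRIAE_CS42_2AL_TGACv1_095785_AA0314520, TRIAE_CS42_2BL_TGACv1_132845_AA0440100 and TRIAE_CS42_2DL_TGACv1_158200_AA0512220) had 0.0508 ± 0.0553, 3.52 ± 0.181 and 10.1 ± 0.621 RPKM, and in endosperm 22.3 ± 2.89, 10.8 ± 0.834 and 4.27 ± 1.37. The difference in A over D was -8.54 (SE 0.36) on the log2 scale at 14 DPA and -8.14 (SE 0.36) at 25 DPA. For WAX2 (TRIAE_CS42_1AL_TGACv1_000860_AA0020560 for A), a protein of cuticle wax synthesis, embryo at 14 DPA had 12 ± 1.53, 0 and 0.109 ± 0.102 RPKM and endosperm 3.72 ± 2.14, 4.06 ± 0.631 and 0.792 ± 0.127. HSC70-1 A over B differed by -6.44 (SE 0.80) at 14 DPA and -7.13 (SE 0.80) at 25 DPA. A dihydroflavonol reductase set (TRIAE_CS42_7BL_TGACv1_579425_AA1907180 for B) differed in A over D by -2.63 (SE 0.20) at 25 DPA. EXPA9 (TRIAE_CS42_5BL_TGACv1_406965_AA1351930 for B) differed in A over D by 2.76 (SE 0.58) at 14 DPA, a call that ended without embryo replicate 1 (2.67) or 2 (2.80). Between embryo stages the B copy of H2A.6 (TRIAE_CS42_6BS_TGACv1_513585_AA1645280) went from 19.2 ± 3.14 RPKM to no read and D (TRIAE_CS42_6DS_TGACv1_542798_AA1730580) from 28.1 ± 3.63 to 1.30 ± 0.245, a change of B over D of -3.25 (SE 0.37) that ended with 1 RPKM added (-0.67). Between endosperm stages A over D of H2A.2.1 (TRIAE_CS42_1AS_TGACv1_019041_AA0058780 for A) changed by 3.40 (SE 0.48), a call that ended without replicates 2 and 3 at 14 DPA (2.22).

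Sets whose ratio differed between tissues numbered 886 of 6445 (13.7%) at 14 DPA and 1720 of 5815 (29.6%) at 25 DPA. Between stages they numbered 374 of 6664 (5.61%) in embryo and 439 of 6122 (7.17%) in endosperm. Without 14 DPA endosperm replicates 2 and 3, which held embryo transcripts, the 4 counts were 1575, 1750, 466 and 238. The 14 DPA tissue count was 570 or 581 without embryo replicate 2 or 3. Without endosperm replicate 1 it was 537, and for endosperm stage 562. That left the pair with embryo transcripts, which cannot rank tissue against stage. In fits of the 6 libraries compared the 4 counts were 574, 1604, 520 and 66. The embryo stage count was 200, 206 or 196 without replicate 1, 2 or 3 at 14 DPA and 221 or 216 without replicate 2 or 3 at 25 DPA. The endosperm stage count was 259 or 275 without replicate 2 or 3 at 14 DPA and 291 or 283 without replicate 2 or 3 at 25 DPA. The nearest pattern was the same in both groups for 82.5 and 74.8% of the sets between tissues and for 83.3 and 81.1% between stages. Of the summed RPKM of the sets, A, B and D held 34.2, 31.6 and 34.2% in 14 DPA embryo and 34.2, 31.3 and 34.5% in 25 DPA embryo. In endosperm they held 35.8, 30.6 and 33.6%, and 35.0, 31.6 and 33.4%. Over both stages the A share was higher by 1.17 points in endosperm and the D share in embryo by 0.865 points (two-sided exact permutation test, 6 against 6 libraries, p = 0.0022 each), and B showed p = 0.29. Without endosperm 14 DPA replicates 2 and 3 the subgenome shares of triad expression, embryo minus endosperm over both stages, differed by -1.13 points for A and 0.988 for D. With each set weighted equally the A difference turned to 0.135 points in favour of embryo and the D difference shrank to 0.154 points.

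**Figure D4:**
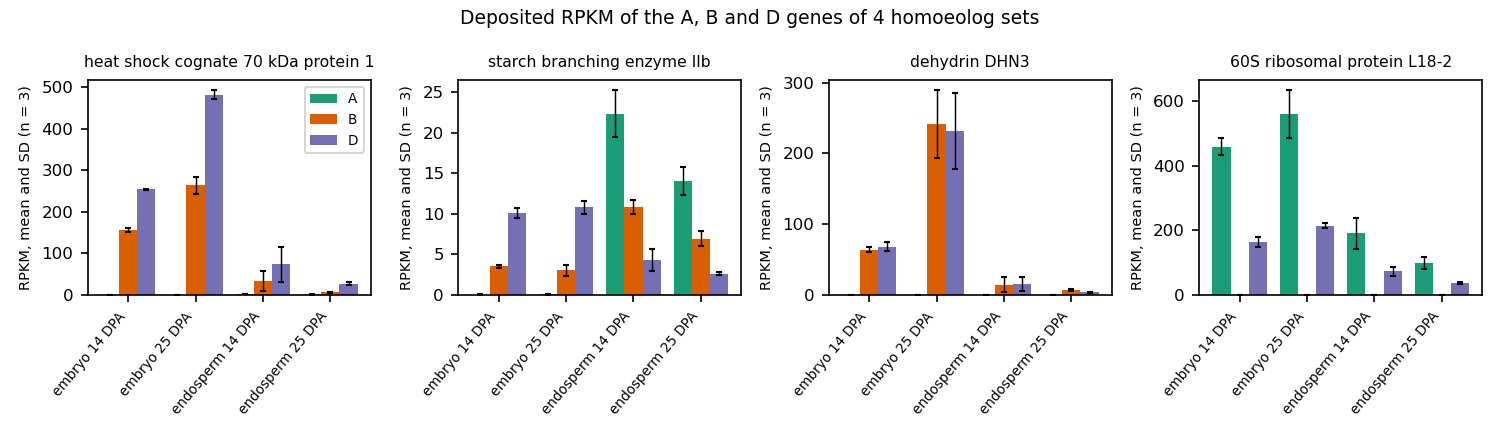
Deposited RPKM of the A, B and D genes of 4 homoeolog sets in each group (mean and SD, n = 3). Starch branching enzyme IIb is led by D in embryo and by A in endosperm, and the other 3 sets have a copy near silence.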

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

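The tests of the embryo and endosperm fractions, of the wider 25 DPA gene set, of carry-over into embryo and of other splits of the libraries were chosen only after the result was seen; the 25 DPA embryo programme test and the chromosome arm tests were written before their values, though the arm itself was singled out from earlier signs.

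The change from 14 to 25 DPA differed between embryo and endosperm in 6552 genes by a test of the interaction. Of 25 assignments of stage within tissue that were drawn, 2 gave as many calls, the real one included, and the highest other gave 11205. That one kept the embryo stages and grouped endosperm replicate 1 at 14 DPA with replicates 2 and 3 at 25 DPA, so the change between embryo stages is still in it. It is no assignment without a change, and the count does not decide on chance. The other drawn assignments that kept the embryo stages gave 1542 and 1606 calls, and those that mixed them 148 at most. Reversing the stage labels in endosperm alone groups the same libraries, so it was not counted; it gave 17005 calls.

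In the full-length transcripts, which no comparison used, 21 of 57424 had a rye secalin gene as nucleotide hit, among 294 with any rye hit. The number that similarity to wheat gliadins would give was not computed, so this count is not a test. They were assigned to A (5), D (14) or no subgenome (2), and 0 to B.

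For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real splits called 14213, 25590, 10645 and 5236 genes, in the order of tissue at 14 and 25 DPA and stage in embryo and endosperm, and the highest other split called 0. For homoeolog ratios the real splits called 574, 1604, 520 and 66 sets, and the highest other 0. In each case 1 split, the real one, reached the count. Every other split puts libraries of both groups on each side, so the group difference enters its spread. The 0 calls therefore do not measure how many calls chance would give.

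Embryo transcripts stood in 2 of the 3 endosperm libraries at 14 DPA, and RNA of 14 DPA embryos in these samples is a candidate explanation. Over 83 genes chosen without those libraries, the upper quartile of the fraction of the embryo level was at most 1.15 times the lower one in replicates 2 and 3, as a single admixed share would need. Library size or scaling is argued against, since embryo genes were higher and endosperm genes lower in replicate 3 than in replicate 1, a difference of 7.22 on the log2 scale. A programme of the 25 DPA embryo cannot be told apart, since only 1 gene (median 0%) and, in the wider set, 2 genes (1.27%) could be tested. An embryo programme of the endosperm at 14 DPA was not tested by itself. The narrow fraction over the 83 genes argues against it as the whole cause for these genes. So does the drop of the 321 endosperm genes, at 106, 64.8 and 44.9% of their 25 DPA level in replicates 1, 2 and 3.

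B homoeologs on the short arm of chromosome 1B were near silent in 62.1% of the sets, and a changed short arm in this cultivar, such as a rye segment, is a candidate explanation. Reads shared between homoeologs or gene models missing by chance are argued against as the whole cause, since the highest share on any other arm was 5.07%. The secalin transcripts stand beside this and do not test it. No genome sequence of the cultivar was used here, so the kind of change stays open, and no biological explanation by group was tested.

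Of the 5835 genes that rose in embryo, 62.6% were more abundant in endosperm at 25 DPA, and carry-over of endosperm RNA is a candidate source for the prolamins. In 25 DPA embryo 37 prolamin genes stood at a median of 0.265% of their endosperm level, with an upper quartile 1.48 times the lower one. Carry-over at the prolamin fraction is argued against as the whole cause, since only 3.80% of the risen genes (222) rose by no more than the highest prolamin fraction of their endosperm level. Photosynthesis genes, markers of green pericarp, stood at a median of 23.4%, and carry-over of episperm or pericarp at a fraction of its own was not measured and is not excluded. A maturation programme shared by both tissues was not tested and stays open.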

How the results depend on the processing

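Results without scaling beyond total reads, without endosperm replicates 2 and 3 at 14 DPA, with a prior count of 0.01, from non-redundant transcripts, and for homoeologs by coding length or without group 1 short-arm sets, were chosen after seeing the data; the cause of a change was not tested unless it is named.

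The number of genes called at 14 DPA, 17186, was 30241 without scaling beyond total reads, 26730 without endosperm replicates 2 and 3, 26060 without a fold threshold and 9046 with a filter of 5 RPKM, which tests fewer genes. With that filter the counts at 25 DPA, between embryo stages and between endosperm stages were 13807, 5377 and 5315. Without a fold threshold the embryo and endosperm stage counts were 16044 and 15176. The endosperm stage count of 9941 was 5236 in a fit of the 6 libraries and 6046 without the 2 libraries. The interaction count ran from 4389 to 11170 when single libraries were left out, the highest without endosperm replicate 1 at 14 DPA. With a replicate block the counts were 17453, 25258, 9449, 9155 and 5778. The other alternatives stayed within 1.5 times.

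Biased homoeolog sets numbered 4898, 5213 and 5089 without a ratio threshold in 14 DPA embryo and in 14 and 25 DPA endosperm. In endosperm they numbered 2061 and 2062 with 1 RPKM added, and 2076 and 1924 with a summed RPKM of 5 or more. Sets with a differing ratio numbered 549, 939 and 249 at that limit, for tissue at 14 and 25 DPA and stage in endosperm. Without endosperm replicates 2 and 3 at 14 DPA they numbered 1575 for tissue at 14 DPA and 238 for stage in endosperm, and with 0.01 RPKM added 233 for stage in embryo. With single libraries left out they ran from 537 to 1191 for tissue at 14 DPA, from 196 to 467 for stage in embryo and from 259 to 562 for stage in endosperm, and in fits of the 6 libraries compared they numbered 574, 1604, 520 and 66, the last for stage in endosperm.

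With an estimated correlation 2, 4, 1, 1 and 2 gene lists were called for tissue at 14 and 25 DPA, stage in embryo and endosperm, and the interaction. Of 110 list tests 61 fell below the threshold that way. With deposited RPKM 9 fell below and 7 passed, and a replicate term changed 0.

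The prolamin share of endosperm at 25 minus 14 DPA turned to -0.126 points without the 2 libraries. With RPKM scaled by median ratios the embryo minus endosperm difference in genes at 1 or more turned to -2178 at 14 DPA and -1614 at 25 DPA. Over both stages it turned to -1896 (exact permutation p = 0.0022), and at 0.5 RPKM it was 3886, no longer past the threshold. With each set weighted equally the A share of embryo minus endosperm turned to 0.0847 at 14 DPA, 0.185 at 25 DPA and 0.135 over both stages, and that of embryo at 25 minus 14 DPA to 0.0154. The B share turned to -0.132 at 14 DPA, -0.289 over both stages and 0.00747 between embryo stages. The D share turned to -0.0229 between embryo stages and weakened to 0.154 over both stages. Between endosperm stages the D share turned to 0.186 without the 2 libraries and ran from -0.324 to 0.0656 with single libraries left out.

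For the named genes, 37 of 2365 recomputed calls ended and 0 reversed; 9 of 96 ended without the 2 libraries and 7 without scaling. For the named homoeolog sets 22 of 1230 ended and 0 reversed. All of these were called in the main fit, and many were named for a large change, so few ended calls were built in. An alternative without a fold threshold could not end a call. These rates do not carry over to the other called genes and sets. The planned pseudocount of 0.1 applied to RPKM alone; counts were used, where the default prior count is close to it, so it was not run.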

Other observations

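The full-length Iso-Seq table, as used here, held 57424 transcripts with a median length of 2526 bases (quartiles 1645 and 3093). Of these 12672 were assigned to A, 13283 to B, 19147 to D and 12322 to none. A rye nucleotide hit was given for 294.

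Among the genes listed, the short arm of 1B held 762, against 966 on the short arm of 1A and 993 on that of 1D, while the long arms held 2520, 2410 and 2465 for 1B, 1A and 1D. Prolamin genes numbered 5, 6 and 9 on the short arms of 1B, 1A and 1D. The B gene was near silent in 62.1% of the sets on the short arm of 1B, the A gene in 0.427% on that of 1A and the D gene in 1.26% on that of 1D.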
